A study of Arabidopsis thaliana with 51 samples.

How the data were processed

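Whole roots of Arabidopsis thaliana were measured by messenger RNA sequencing, and 47 libraries from 51 sample records were used. Per the labels, RNA was extracted with TRIzol and treated with DNase, and libraries were made with the Illumina TruSeq stranded protocol. The authors deposited a single table of raw read counts per gene, with 32833 genes and a column for each library. Its values are whole numbers with no normalization. The submitters' notes name fastp 0.20.0, FastQC 0.11.9, MultiQC 1.19, STAR 2.7.10a and DESeq2 (no version) with the genome build TAIR10. The counting program, its strand setting and its handling of reads shared between genes are not given in the sources used here. Counts of overlapping genes, antisense transcripts and close paralogs are therefore uncertain. The families concerned here include RBCS, LHCB1, PDF1.2, IGMT and GSTU, and PAI1 with its copy PAI2. A total of 4 libraries were sequenced in 2 runs, and each has a single column in the table, so it was used as a single sample.

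Groups were formed from the genotype, treatment and day in the labels. The 16 groups held 3 libraries each, except SiBs in T530 at day 6 with 2. Groups missing from the crossed design were not analysed here: Bs at day 6, Si and Bs alone in Col-0, Col-0 at day 6, and the third SiBs library of T530 at day 6. The labels do not say whether replicates are separate plants, plates or cultures, so the p-values measure the spread between these samples. Replicate numbers did not pair the samples. Residual correlations between libraries of the same number and genotype on the same day ran from -0.26 to 0.21, so no pairing was used. Gene names, and the transcript lengths of 1 check, came from the TAIR10.1 annotation, which matched 32548 of the 32833 identifiers. No positions are given, because the deposited counts were made on TAIR10.

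Tests were run in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed by group (filterByExpr), leaving 26150 tested genes. Libraries were scaled by TMM, and 1 quasi-likelihood model with a mean for each group was fitted to all 47 libraries. P-values were adjusted by the Benjamini-Hochberg method over all tested genes within each comparison, with a threshold of 0.05. A gene is said to have risen, fallen or changed only past that threshold. Gene values are log2 fold changes ± standard error (SE), and group levels are CPM (counts per M). Total counts ran from 28.1 to 103.8 M per library, where M is the prefix mega. The common biological coefficient of variation was 0.171. Floors cover counting error only, while the SE also takes in the spread between libraries.

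A gene whose libraries were all at 0 in a compared group is given as "at least" a fold, against a floor of 3 counts over that group. On data simulated from these counts with 3 against 3 libraries, the test recovered 35 of 67 genes changed 2-fold and 63 of 66 changed 4-fold, with 3 false calls. For a difference between genotypes in the response it recovered 10 of 67 and 50 of 66, with 2 false calls. The simulation fitted only Mock and Bs of day 3 in T510 and T530 and changed few of its 24164 genes. All changed genes had an expected mean of at least 50 counts, so the rates do not cover genes with lower counts. In the real data most genes changed with Bs and all 47 libraries were fitted, so these rates do not carry over directly. Smaller differences in response were often missed in the simulation, and may be missed here.

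A total of 27 gene lists with 344 members were fixed before the data were examined. They cover camalexin and indole cyanogenic synthesis, tryptophan synthesis, indole glucosinolates, aliphatic glucosinolates, early markers of pattern-triggered immunity, immune receptors and their partners, salicylic acid, jasmonate, ethylene and jasmonate-ethylene defence, chitinases, phenylpropanoids and lignin, and suberin. Others hold markers of the endodermis, root hairs, vasculature, dividing cells, developmental cell death with the root cap, and photosynthesis (shoot tissue). The rest are phosphate starvation, nitrogen uptake, iron deficiency, hypoxia, triterpenes, detoxification, sugar transport, abscisic acid and reference genes. Each list was tested against all other genes with camera (limma 3.58.1) with its inter-gene correlation estimated, and adjusted over the 27 lists of each comparison. Unless stated otherwise, adjusted p-values of lists are these. Of the 783 list tests, 58 passed. With a preset correlation of 0.01, 328 passed, and with fry, which asks whether a list's genes move on balance one way, 384 passed. The 58 were among both. Counts of members "adjusted over the list alone" use Benjamini-Hochberg within the list. List medians were recomputed with genes at 0 in a group set to their bound, and the second median is given where it differs.

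Named genes follow a rule fixed before the data were examined: up to 4 called members of each list with the largest change, the 5 most risen and 5 most fallen genes with a mean of at least 5 CPM and no overlap between the libraries compared, and always PR1, ICS1, PAD3, CYP71A12, PDF1.2A, WRKY33 and FRK1. The 200 genes raised and the 200 lowered by Bs with the smallest p in each genotype were also followed in the other genotype's comparisons. Their camera p-values were adjusted over all tests of these 200-gene lists together. A total of 6 further lists (morning and evening clock genes, photorespiration and leaf markers, dark-inducible genes, heat shock, autophagy) were chosen after the data were examined. Their p-values were adjusted over these 6 lists in each comparison.

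Alternatives were RLE size factors, no filter and a stricter filter (50 counts in 3 libraries), DESeq2 1.42.0, a replicate block, leaving out the 4 libraries with 2 runs, fitting only the libraries compared, leaving out each library in turn, and other set tests. Thinning all libraries to the depth of the shallowest, and counting only genes whose Mock level did not differ between days in T510, were chosen after seeing the data. The tolerances used to compare alternatives were chosen by the analyst before the alternatives were seen: 0.1 for correlations and the interquartile range of the list, halved, for medians of the 200-gene lists.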

Results

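The experiment measured gene expression in whole roots of 3 Arabidopsis genotypes, the reference accession Col-0 and the lines T510 and T530, which the labels name only by these codes. Roots were treated with water (Mock), with Serendipita indica (Si), a fungus that colonises roots as an endophyte, with Bipolaris sorokiniana (Bs), a fungal pathogen best known from cereals, or with both fungi (SiBs). They were taken 3 or 6 days after infection. The study's title asks whether the endophyte extends host immunity and evens out natural variation in it. T510 and T530 had Mock, Si, Bs and SiBs at day 3 and Mock, Si and SiBs at day 6, and Col-0 had Mock and SiBs at day 3. Each group had 3 libraries, except T530 SiBs at day 6 with 2.

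Library totals ran from 28.1 to 103.8 M counts. The Bs libraries were shallower than Mock, with 43.2 to 66.3 M in T510 and 28.1 to 39.2 M in T530, against 80.4 to 93.9 and 87.0 to 103.8 M in Mock of day 3. The first principal component held 37.7% of the variance and the second 17.8%. On the first, Mock libraries of T510 at day 3 averaged -102.2, Si -26.4, SiBs 20.3 and Bs 164.3, and T530 gave the same order with -78.9, -16.4, 46.0 and 235.7. Summed expression of 11 photosynthesis genes, markers of shoot tissue, varied between libraries from 21.4 to 1774 CPM, with the highest value in Col-0 Mock replicate 1.

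**Figure D1:**
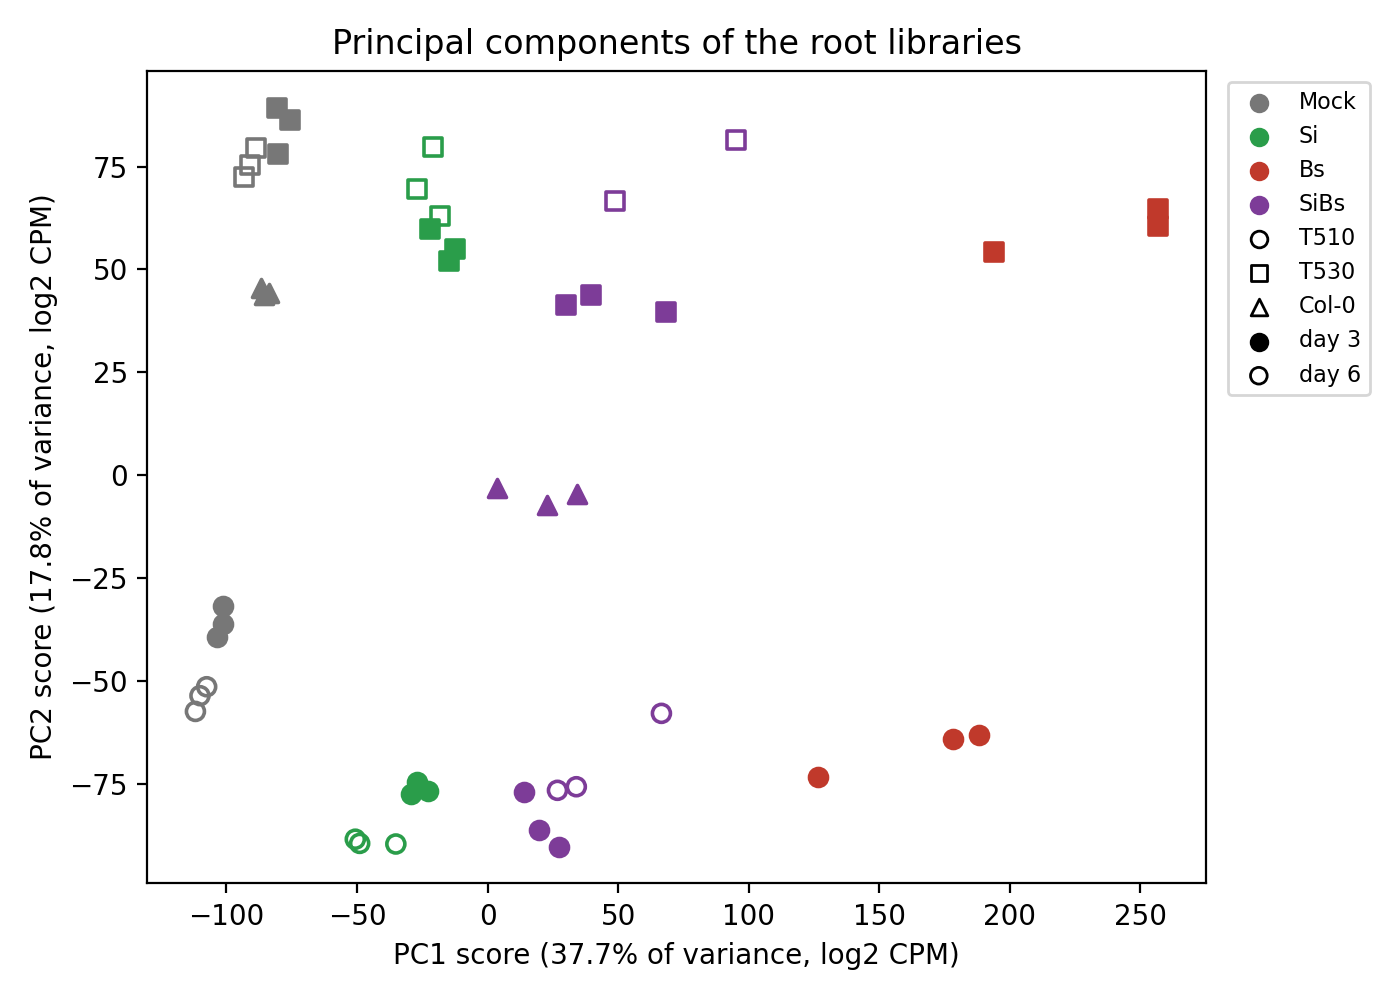
Scores of each of the 47 libraries on the first and second principal components of log2 CPM, with colour for treatment, symbol shape for genotype, and filled symbols for day 3. Along the first component Bs libraries of day 3 lie farthest from Mock (means 164.3 and -102.2 in T510), with Si and SiBs between them.

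The comparison of Bs with Mock asks how roots respond to the pathogen alone. After 3 days, Bs raised all 10 measured genes of camalexin and indole cyanogenic synthesis in both T510 and T530, the pathway to the main indole phytoalexin. CYP71A13, which makes the camalexin precursor indole-3-acetonitrile, rose by 13.31 ± 0.74 log2 in T510 and 12.33 ± 0.69 in T530, and PAD3, the last step to camalexin, by 7.82 ± 0.40 and 6.86 ± 0.38 (n = 3 per group). Mock levels of CYP71A13 at day 3 were near 0, from 0.0401 to 0.150 CPM in T510 and 0.0386 to 0.468 in T530. At the same time, most measured genes of dividing cells, the endodermis, root hairs and aliphatic glucosinolates fell, in lists that did not pass with an estimated correlation (counts and adjusted p below). In all, 17392 of 26150 genes changed in T510 (9018 rose and 8374 fell) and 18746 in T530 (9081 rose and 9665 fell), of which 15178 passed in both and 14939 of those moved the same way.

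The camalexin list had a median of 8.01 in T510 and 7.28 in T530 (adjusted p = 0.0432 and 0.0703 with an estimated correlation). Tryptophan synthesis, its supply, had 8 of 9 genes up in each genotype, led by the anthranilate synthase ASA1 (4.33 ± 0.19 and 4.78 ± 0.20; adjusted p = 0.0443 and 0.0703 with an estimated correlation). All 16 detoxification genes rose in both, among them the glutathione transferase GSTU12 (9.03 ± 0.44 and 9.16 ± 0.43) and the glucosyltransferase UGT74E2 (7.08 ± 0.41 and 7.11 ± 0.41; adjusted p = 0.0432 and 0.0703 with an estimated correlation). Adjusted over the list alone, the counts of all 27 lists in this comparison were the same, except where given. Among indole glucosinolate genes 12 rose and 4 fell of 19 in T510, and 12 and 5 in T530 (adjusted p = 0.293 and 0.513). MYB51, an activator of the pathway, rose by 4.31 ± 0.19 and 3.98 ± 0.19. Aliphatic glucosinolate genes went the other way, with 10 of 14 lower in T510 and 11 in T530 (adjusted p = 0.265 and 0.11 with an estimated correlation). MAM1, which elongates methionine in that pathway, fell (-4.52 ± 0.40 in T510 and -8.37 ± 0.59 in T530).

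Of 19 early markers of pattern-triggered immunity, 18 rose in each genotype, including NHL10 (9.06 ± 0.48 and 8.31 ± 0.46), WRKY33 (3.70 ± 0.20 and 4.06 ± 0.21) and FRK1 (2.95 ± 0.26 and 2.38 ± 0.27; list adjusted p = 0.0941 and 0.11 with an estimated correlation). Of 15 receptor and partner genes, 12 rose in T510 and 13 in T530, such as the NADPH oxidase RBOHD (3.74 ± 0.14 and 3.33 ± 0.14; adjusted p = 0.0941 and 0.0703). Jasmonate genes rose in 17 of 21 cases in both, with the repressor gene JAZ8 at 5.18 ± 0.44 and 8.39 ± 0.54 and the lipoxygenase LOX3 at 9.02 ± 0.69 and 8.17 ± 0.61 (adjusted p = 0.166 and 0.128). Of 17 ethylene and jasmonate-ethylene defence genes, 12 rose in T510 and 16 in T530, such as the ethylene synthesis gene ACS6 at 5.11 ± 0.21 in T510 (adjusted p = 0.132 and 0.11). PDF1.2A, a defensin gene at 0 in Mock of both genotypes, was at least 242-fold higher in T530, and did not pass in T510. The salicylic acid list split, with 7 genes up and 3 down of 19 in T510 and 6 up and 4 down in T530 (adjusted p = 0.845 and 0.657). ICS1, the main salicylic acid synthesis gene, fell (-1.11 ± 0.31 in T510) and measured -0.69 ± 0.32 in T530, which did not pass (without T530 Bs replicate 1 it measured -0.87 and passed). ALD1, which makes the systemic signal pipecolic acid, fell (-3.31 ± 0.66 and -3.97 ± 0.80). Chitinases rose in 8 and 7 of 8 cases (adjusted p = 0.132 and 0.251).

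Stress and nutrition lists followed. Hypoxia genes rose in 9 of 10 cases in each genotype, with alcohol dehydrogenase ADH1 at 4.81 ± 0.33 and 4.69 ± 0.33 (adjusted p = 0.0846 and 0.0703). Abscisic acid genes rose in 7 and 5 of 8 cases, with the phosphatase HAI1 at 4.91 ± 0.35 and 5.12 ± 0.35 (adjusted p = 0.222 and 0.462). Phenylpropanoid and lignin genes rose in 12 and 10 of 15 cases (11 adjusted over the list alone in T530; adjusted p = 0.286 and 0.453). Iron deficiency genes split into 9 risen and 6 fallen of 21 in T510 and 5 and 11 in T530: the iron transporter IRT1 fell (-6.63 ± 0.86 in T510), while the signal peptide gene IMA3 rose by 13.05 ± 0.66 and 12.57 ± 0.62 (list adjusted p = 0.724 and 0.657). Phosphate starvation (8 up and 5 down of 16 in T510, adjusted p = 0.607), nitrogen uptake (4 and 6 of 14, 0.961) and sugar transport (4 and 3 of 8, 0.866) were mixed. In T530, phosphate starvation genes gave 8 up and 7 down (8 adjusted over the list alone), nitrogen uptake 3 and 9, and sugar transport 4 and 2. Median, mean and test differ in sign for nitrogen uptake in T510 and for sugar transport in both genotypes. The sugar transporter gene STP13 rose by 4.51 ± 0.26 and 4.22 ± 0.26.

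All 7 markers of dividing cells fell in both genotypes, the mitotic cyclin CYCB1-2 (-2.77 ± 0.16 and -3.47 ± 0.17, list adjusted p = 0.0941 and 0.11 with an estimated correlation). All 8 endodermis markers fell (list adjusted p = 0.293 and 0.359). Of 7 root hair markers, 6 fell in T510 and all in T530, COBL9 (-2.88 ± 0.47 and -5.32 ± 0.59, list adjusted p = 0.48 and 0.355). Triterpene cluster genes fell in 8 and 7 of 9 cases (adjusted p = 0.178 and 0.251). Vascular markers fell in 8 of 11 cases in each (0.353 and 0.251), and genes of developmental cell death and the root cap in 9 of 13 (0.286 and 0.453). Suberin genes were mixed, with 4 up and 1 down of 10 in T510 and 1 up and 5 down in T530 (0.866 and 0.777). Photosynthesis genes rose in 2 of 11 cases in T510 (0 adjusted over the list alone) and fell in 8 in T530 (0.918 and 0.657). Reference genes moved too: UBQ10 rose by 1.38 ± 0.12 and 1.27 ± 0.12, and ACT2 fell (-1.06 ± 0.11 in T510, list 4 up and 1 down of 6 in T510, adjusted p = 0.733). Among the largest changes outside the lists, the cytochrome P450 gene CYP71B21 was at least 15549-fold higher in T510 and at least 15796-fold in T530, and the arabinogalactan protein gene AGP30 was at least 5331-fold lower in T510. With a preset correlation most of these list results pass; with an estimated correlation only camalexin, tryptophan and detoxification did, in T510.

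**Figure D2:**
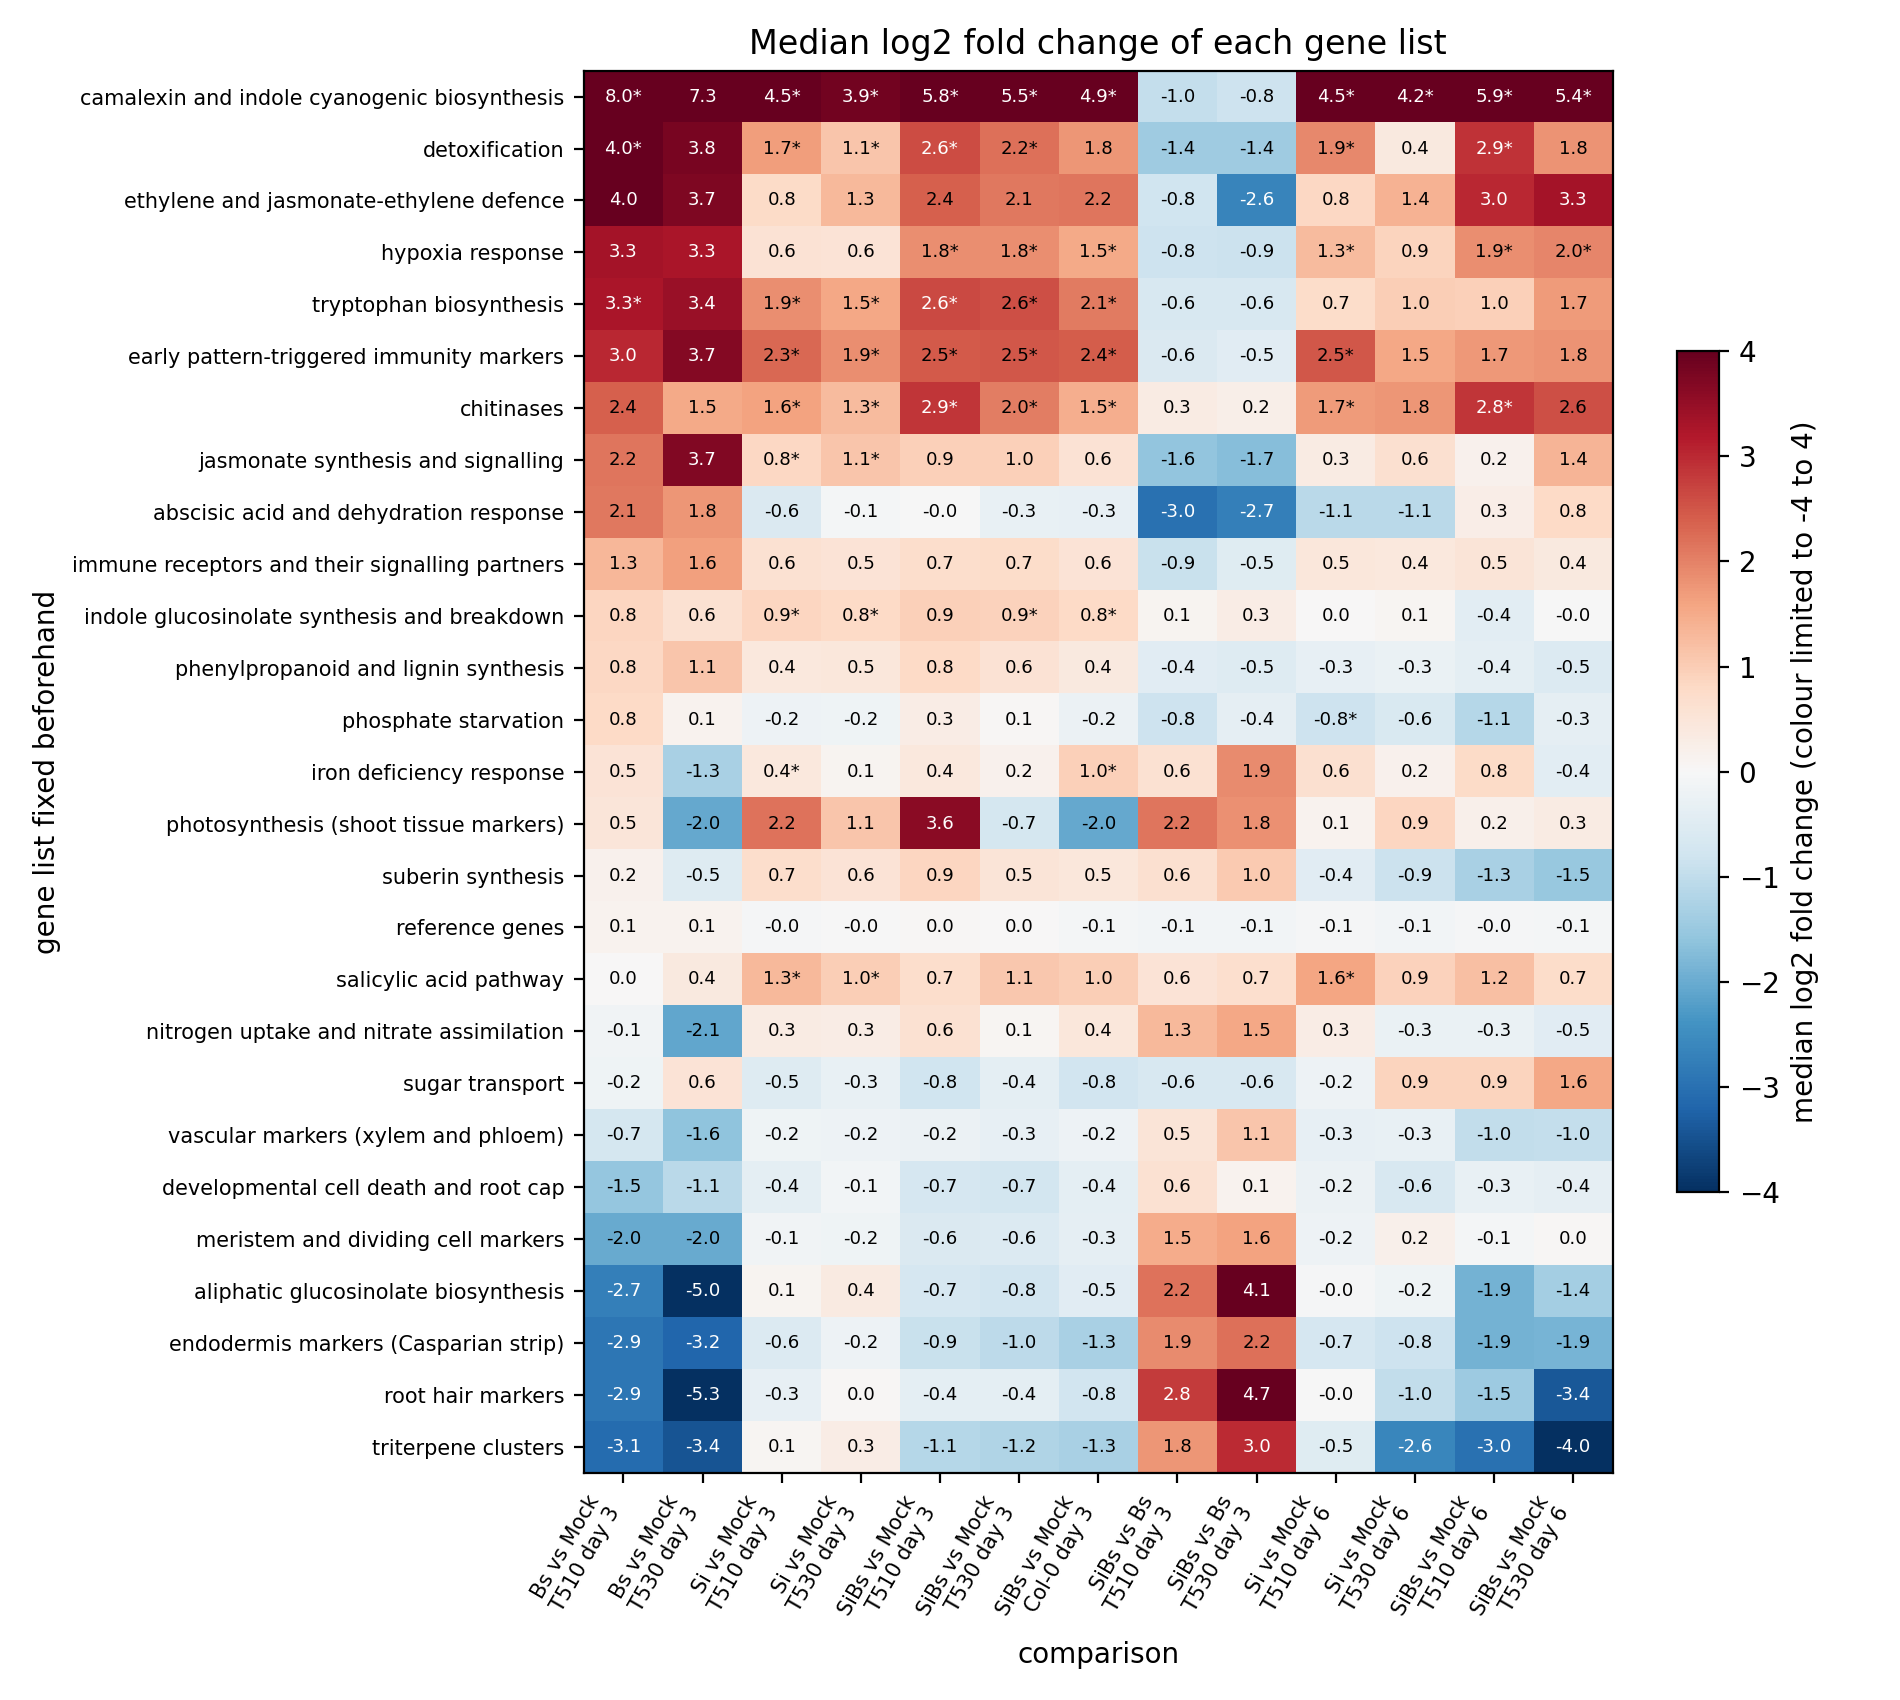
Median log2 fold change of each of the 27 gene lists in 13 comparisons, with an asterisk where the list's adjusted p with an estimated correlation is under 0.05. In Bs against Mock of T510, camalexin genes have a median of 8.01 and endodermis markers -2.88.

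The comparison of Si with Mock at day 3 asks how roots respond to the endophyte alone. Si raised all 10 camalexin genes in both lines, as Bs did, and CYP71A13 rose by 11.68 ± 0.72 in T510 and 10.01 ± 0.65 in T530 (n = 3 per group). Markers of pattern-triggered immunity, the first layer of response to microbes, rose almost without exception. Salicylic acid genes, which Bs did not move together, rose with Si: ICS1 by 1.52 ± 0.30 and 1.18 ± 0.30, and its regulator CBP60g by 4.36 ± 0.28 and 3.24 ± 0.27. Fewer genes moved than with Bs: 4616 in T510 (3208 rose and 1408 fell) and 2995 in T530 (2569 rose and 426 fell), with 2358 in both and 2355 of those the same way. With only the compared libraries fitted they were 7145 and 4879.

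Of the lists, camalexin had medians of 4.53 and 3.86 (adjusted p = 1.1e-05 and 3.9e-06), and early immunity markers rose in 19 of 19 and 18 of 19 cases (1.8e-04 and 2.1e-04), with the peroxidase gene PER5 at 5.99 ± 0.46 and 6.92 ± 0.49 and FRK1 at 3.16 ± 0.26 and 3.43 ± 0.26. Tryptophan genes rose in 8 of 9 and 7 of 9 (8 adjusted over the list alone) (7.6e-04 and 8.7e-04), indole glucosinolate genes in 13 of 19 (15 adjusted over the list alone) and 13 of 19 (14 adjusted over the list alone) (0.00307 and 0.00278), such as CYP81F2 (3.44 ± 0.23 and 2.71 ± 0.23). Chitinases rose in 5 of 8 (6 adjusted over the list alone) and 5 of 8 (0.00261 and 6.7e-04), led by AT2G43570 (4.73 ± 0.24 and 4.72 ± 0.23). Detoxification genes rose in 14 of 16 (16 adjusted over the list alone) and 13 of 16 (14 adjusted over the list alone) (0.00621 and 0.0125), salicylic acid genes in 10 of 19 (12 adjusted over the list alone) and 11 of 19 (13 adjusted over the list alone) (0.0156 and 0.0129), and jasmonate genes in 14 of 21 and 14 of 21 (0.0187 and 0.0223). Among the last, LOX4 rose by 5.68 ± 0.40 and 4.88 ± 0.38. Iron deficiency genes passed in T510 only, with 9 of 21 up (adjusted p = 0.0379 against 0.423 in T530), where IMA1 rose by 4.50 ± 0.66 and IMA2 by 3.37 ± 0.51. IMA3 rose in both (11.34 ± 0.64 and 10.13 ± 0.59). Of the genes that fell, the sugar exporter SWEET12 fell (-3.69 ± 0.69 in T510) and the phosphate-responsive RNA AT4 (-1.47 ± 0.26 and -2.39 ± 0.27). WRKY33 rose by 2.07 ± 0.19 and 1.67 ± 0.19, PAD3 by 4.18 ± 0.34 and 2.90 ± 0.32.

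With both fungi together (SiBs against Mock, day 3) the 3 genotypes, now including Col-0, responded along the same lines. CYP71A13 rose by 11.73 ± 0.72 in T510, 10.25 ± 0.65 in T530 and 10.71 ± 0.77 in Col-0, and all 10 camalexin genes rose in each (n = 3 per group). The level of CYP71A13 in SiBs was lower in Col-0, 28.8 to 67.5 CPM against 237 to 321 in T510 and 175 to 342 in T530. This difference in level was not tested. The fold changes start from Mock levels near 0, in Col-0 from 0.0108 to 0.0417 CPM. ICS1, which Bs alone did not raise, rose by 1.88 ± 0.30, 1.79 ± 0.30 and 1.41 ± 0.30. All 19 early immunity markers rose in each genotype. The genes changed numbered 13747 (7395 up), 12985 (6800 up) and 12521 (6487 up), with 9578 in both T510 and Col-0 (9408 the same way) and 9484 in both T530 and Col-0 (9442 the same way).

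In the order T510, T530 and Col-0, list results were camalexin (median 5.80, 5.54 and 4.91; adjusted p = 0.0017, 8.3e-04 and 8.3e-04), early immunity (0.00667, 0.00988 and 0.00677) and tryptophan (9 of 9, 8 of 9 and 9 of 9 up; 0.00667, 0.00987 and 0.00677). Hypoxia genes rose in 9 of 10, 9 of 10 and 8 of 10 (9 adjusted over the list alone) (adjusted p = 0.0237, 0.0137 and 0.0213), ADH1 by 3.72 ± 0.31, 3.57 ± 0.31 and 3.63 ± 0.31. Chitinases rose in 8 of 8, 8 of 8 and 5 of 8 (6 adjusted over the list alone) (adjusted p = 0.00667, 0.0167 and 0.0404), and detoxification genes in 16 of 16, 15 of 16 and 14 of 16 (0.00667, 0.0122 and 0.0512). Indole glucosinolate genes passed in T530 and Col-0 (0.0371 and 0.0324, against 0.0593 in T510), and iron deficiency genes in Col-0 alone (15 of 21 (16 adjusted over the list alone) up, 0.0324, against 0.103 and 0.476), with BHLH100 at 5.47 ± 0.77. The cyclin CYCB1-2 fell (-0.94 ± 0.15, -1.04 ± 0.15 and -0.60 ± 0.15). The triterpene gene MRN1 fell (-3.37 ± 0.81, -3.18 ± 0.82 and -2.71 ± 0.80). Photosynthesis genes rose in 11 of 11 in T510 and fell in 8 of 11 (10 adjusted over the list alone) in Col-0, with list adjusted p = 0.601 and 0.56 with an estimated correlation. Their summed levels were 860.5 CPM in T510 SiBs replicate 2 and 1774 CPM in Col-0 Mock replicate 1. The photorespiration and leaf markers, chosen after the data were examined, rose in 7 of 9 cases in T510 (median 1.87). Their sums in Col-0 were 528 to 870 CPM in Mock and 389 to 454 in SiBs. As a list they did not pass in T510 or Col-0 either (adjusted p = 0.798 and 0.718).

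The comparison of SiBs with Bs asks what the endophyte changes in roots that also carry the pathogen. Several salicylic acid and pipecolic acid genes were higher with the endophyte: ICS1 by 2.99 ± 0.32 in T510 and 2.49 ± 0.33 in T530, FMO1, which makes the systemic signal N-hydroxypipecolic acid, by 4.39 ± 0.58 and 4.47 ± 0.65, and ALD1 by 3.89 ± 0.67 and 4.50 ± 0.80 (n = 3 per group). The jasmonate gene JAZ8 (-3.13 ± 0.39 and -3.56 ± 0.40) and the abscisic acid gene RD29B (-5.17 ± 0.76 and -4.53 ± 0.75) were lower. Higher were EXPA7 of root hairs by 2.90 ± 0.45 and 5.84 ± 0.63, KNOLLE of dividing cells by 1.98 ± 0.17 and 2.19 ± 0.18, and MAM1 by 2.94 ± 0.39 and 7.12 ± 0.60. Summed photosynthesis genes, markers of shoot tissue, ran from 164 to 258 CPM in SiBs and 21.4 to 57.7 in Bs of T530. In T510 they ran from 106 to 860.5 and from 68.7 to 119. A different amount of shoot tissue could therefore give part of the difference between SiBs and Bs, which was not tested. The genes changed numbered 16481 in T510 (8382 rose and 8099 fell) and 17710 in T530 (9518 rose and 8192 fell), with 13939 in both and 13773 of those the same way.

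No list passed with an estimated correlation, and the member counts are given with that limit. Of 19 salicylic acid genes, 10 rose and 4 fell in T510 and 11 rose and 3 fell in T530 (adjusted p = 0.479 and 0.616 with an estimated correlation). Abscisic acid genes fell in 7 of 8 and 7 of 8 (adjusted p = 0.417 and 0.377 with an estimated correlation), jasmonate genes in 14 of 21 and 17 of 21 (0.476 and 0.377) and detoxification genes in 14 of 16 and 15 of 16 (0.476 and 0.404). Root hair markers rose in 7 of 7 and 7 of 7 (0.476 and 0.404), aliphatic glucosinolate genes in 10 of 14 and 11 of 14 (0.476 and 0.377), endodermis markers in 7 of 8 and 7 of 8 (0.476 and 0.462) and dividing cell markers in 6 of 7 and 7 of 7 (0.473 and 0.377). Camalexin genes fell in 7 of 10 and 7 of 10: PAD3 (-2.67 ± 0.32 and -2.73 ± 0.32), while CYP71A12 did not pass in either (-0.17 ± 0.26 and -0.17 ± 0.26). Immunity markers split, with NHL10 lower (-3.78 ± 0.37 and -3.73 ± 0.37) and PROPEP3 (-1.92 ± 0.30 and -2.06 ± 0.30). The nitrate transporter NRT2.1 rose by 4.94 ± 0.71 and 4.56 ± 0.70.

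The Bs response was then followed across genotypes, so that no Bs library served both to choose the genes and to test them. Adjusted p-values of these 200-gene lists are over all their tests together. Of the 200 genes raised by Bs in T510 with the smallest p, 188 were lower and 1 was higher in SiBs than in Bs in T530 (median -1.61, adjusted p = 0.0209). Of the 200 lowered genes chosen the same way, 197 were higher (1.88, 0.00702). With the genotypes exchanged, 183 of the raised genes were lower and 2 higher in T510 (-1.45, 0.0181), and 198 of the lowered genes were higher (1.46, 0.00702). Over all called genes the medians were smaller, -0.69 and 1.00 for genes raised and lowered in T510, and -0.62 and 0.63 in T530. Most still differed from Mock. In SiBs against Mock, 197 and 195 of the raised genes were up (2.05 and 2.01; adjusted p = 5.9e-04 and 9.4e-04) and 177 and 166 of the lowered genes were down (-0.84 and -0.68; 0.0147 and 0.0573, so the second list did not pass). In Si against Mock, 171 and 177 of the raised genes were up (1.23 and 1.41; 4.2e-04 in both), while 25 and 44 of the lowered genes were down, in lists that did not pass (0.149 and 0.226). CYP71A13 was lower in SiBs than in Bs (-1.57 ± 0.42 and -2.08 ± 0.43).

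**Figure D3:**
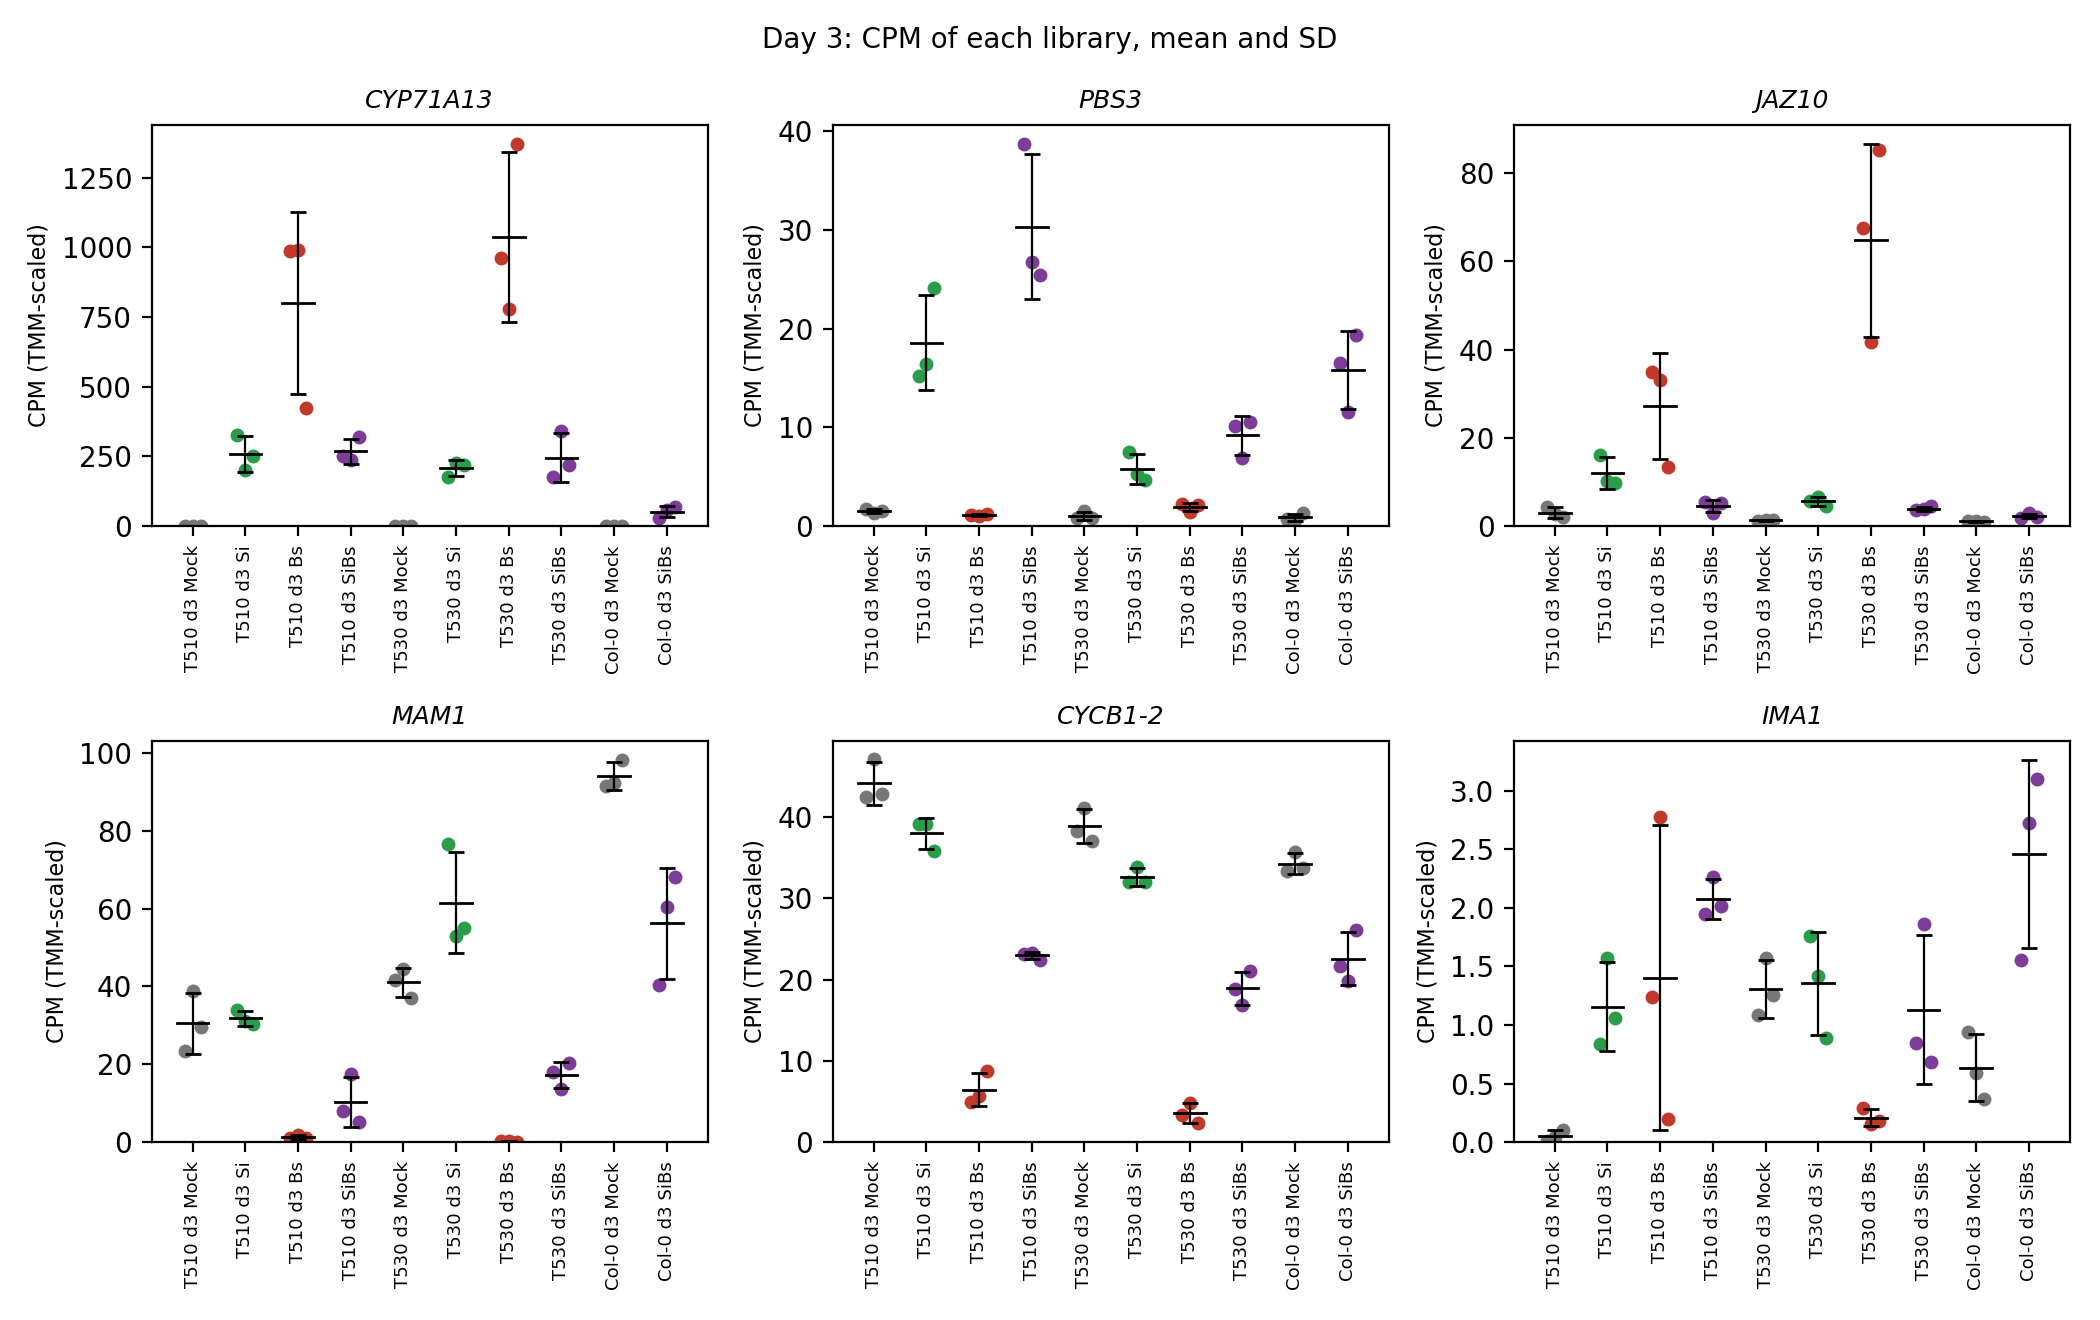
Mean and standard deviation of CPM of CYP71A13, PBS3, JAZ10, MAM1, CYCB1-2 and IMA1 in each genotype and treatment at day 3, with each library as a point (n = 3). MAM1 and CYCB1-2 are lowest in Bs and lie between Bs and Mock in SiBs.

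Compared with Si alone at day 3, adding the pathogen raised fermentation genes in both lines. ADH1 rose by 3.03 ± 0.30 in T510 and 2.74 ± 0.30 in T530 and PDC1 by 3.54 ± 0.35 and 3.12 ± 0.34 (n = 3 per group), and the hypoxia list, which holds them, had 7 of 10 (8 adjusted over the list alone) and 8 of 10 genes up (adjusted p = 0.0351 in T510 and 0.0585 in T530). ICS1 did not pass in either (0.36 ± 0.29 and 0.61 ± 0.29). Detoxification genes rose in 13 of 16 (14 adjusted over the list alone) and 14 of 16 (adjusted p = 0.21 and 0.281), UGT74E2 by 2.77 ± 0.33 and 2.74 ± 0.33, and the isocitrate lyase gene ICL by 4.33 ± 0.66 and 4.71 ± 0.67. Triterpene genes fell in 8 of 9 and 7 of 9 (0.122 and 0.281), and MAM1 (-1.63 ± 0.33 and -1.83 ± 0.32). The genes changed numbered 7302 in T510 and 9536 in T530. The first was 4244 without T510 SiBs replicate 1 and 8285 without replicate 2, the library with the most shoot markers of its group. With only the compared libraries fitted it was 4725.

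At day 6 the endophyte alone still raised the camalexin pathway. CYP71A13 rose by 8.17 ± 0.64 in T510 and 11.60 ± 0.79 in T530, PAD3 by 4.57 ± 0.35 and 3.38 ± 0.33, and the camalexin list passed in both (7 of 10 and 7 of 10 up; adjusted p = 5.3e-04 and 0.0198; n = 3 per group). CYP71A13 was near 0 in Mock, at 0.0260 to 0.220 CPM in T510 and 0 to 0.0477 in T530. With Si it ran from 36.6 to 41.3 CPM in T510 and from 32.5 to 117 in T530. Its larger fold change in T530 thus rests partly on the lower Mock level. In T510, phosphate starvation genes fell in 12 of 16 (13 adjusted over the list alone) (adjusted p = 0.00101), among them SPX1, a marker of phosphate shortage (-3.25 ± 0.30), from a Mock level of 57.4 CPM against 9.68 at day 3. In T530 they fell in 9 of 16, in a list that did not pass (0.0755). Early immunity markers rose in 17 of 19 (18 adjusted over the list alone) in T510 and 18 of 19 in T530 (5.3e-04 and 0.0624). Further lists that passed in T510 were detoxification (16 of 16 up, 0.00294), chitinases (5 of 8, 0.00455), salicylic acid (13 of 19 (14 adjusted over the list alone), 0.00632) and hypoxia (7 of 10 (8 adjusted over the list alone), 0.0123). In T530 these gave 0.443, 0.063, 0.19 and 0.0755. The triterpene gene THAS1 fell (-3.42 ± 0.29 in T530). Si changed 4656 genes in T510 and 8954 in T530 (5558 without the 4 libraries with 2 runs). Of 10 clock genes, chosen after the data were examined, 6 changed in T510, in lists that did not pass, and all 10 in T530. LHY fell (-1.25 ± 0.24 in T510, chosen after its value was seen, and -4.97 ± 0.29 in T530). Treated roots may have been taken at another time of day than their Mock, which the labels do not give. That could give part of the genes changed at day 6, above all in T530, and the tests below do not settle it. The same limit holds for SiBs against Mock at day 6.

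**Figure D4:**
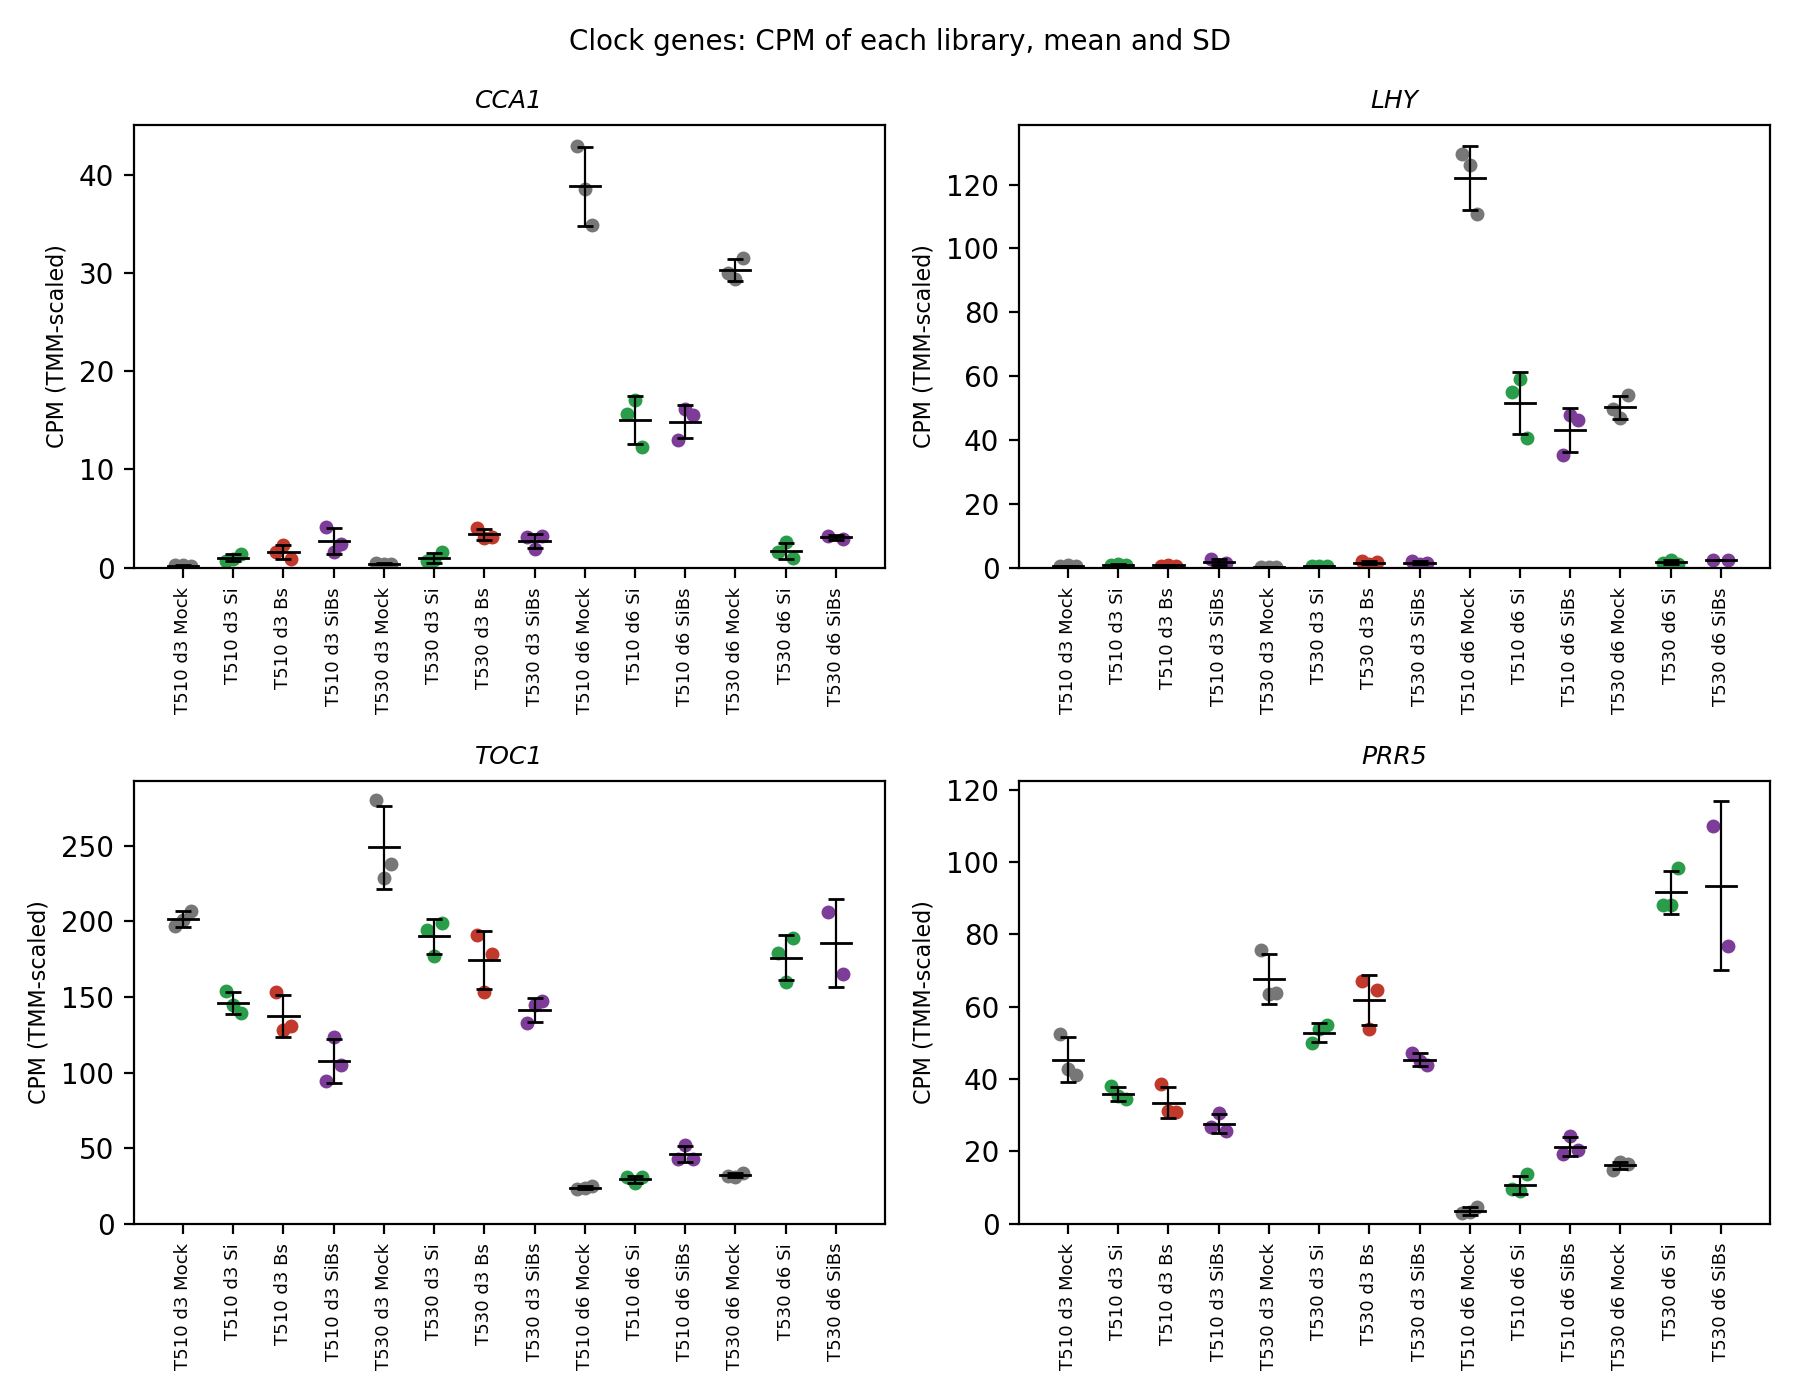
Mean and standard deviation of CPM of CCA1, LHY, TOC1 and PRR5 in each group of T510 and T530, with libraries as points (n = 3, and 2 for T530 SiBs at day 6). TOC1 of T530 at day 6 is 32.1 CPM in Mock and 176 in Si.

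With both fungi at day 6, hypoxia and camalexin genes rose in both lines. PDC1 rose by 5.02 ± 0.37 in T510 (n = 3) and 3.12 ± 0.36 in T530 (n = 2 for SiBs), and the hypoxia list had 10 of 10 and 9 of 10 up (adjusted p = 0.0147 and 0.0348). CYP71A13 rose by 10.31 ± 0.68 and 13.95 ± 0.82, and the camalexin list passed (0.0185 and 0.022). From the Mock levels near 0 given above, CYP71A13 reached 117 to 248 CPM in T510 SiBs and 253 to 439 in T530 SiBs. PR2, a salicylic acid marker, rose by 4.12 ± 1.03 and 6.55 ± 1.25, while ICS1 did not pass (-0.19 ± 0.29 and -0.29 ± 0.34). PR1, a further marker, passed on a single SiBs library in each line. In T510 it was at 0 in Mock and from 0 to 2.00 CPM in SiBs, at least 60.3-fold higher, and was too low to be tested without T510 SiBs replicate 1. In T530 it ran from 0.0374 to 3.80 CPM in SiBs and did not pass without T530 SiBs replicate 1 (adjusted p = 0.494). At day 3, and in Si against Mock at day 6, PR1 had at most 2 counts in any group and passed nowhere. Detoxification and chitinase genes passed in T510 (0.0185 and 0.0147, against 0.188 and 0.06 in T530). Endodermis markers fell in 7 of 8 and 7 of 8 (0.314 and 0.351) and suberin genes in 8 of 10 and 8 of 10 (0.354 and 0.347), CYP86A1 (-2.56 ± 0.47 and -2.43 ± 0.55). The genes changed numbered 13008 and 12502, the latter 7919 without T530 SiBs replicate 1, when a single SiBs library remains.

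Against Si alone at day 6, most aliphatic glucosinolate genes were lower and most abscisic acid genes higher with the pathogen added, in lists that did not pass. MAM1 fell (-2.58 ± 0.34 in T510 and -2.54 ± 0.39 in T530), and its list fell in 13 of 14 and 10 of 14 (adjusted p = 0.082 and 0.158 with an estimated correlation; n = 3 per group, 2 for T530 SiBs). HAI1 rose by 2.97 ± 0.32 and 2.99 ± 0.34, with 7 of 8 and 6 of 8 (7 adjusted over the list alone) abscisic acid genes up (0.184 and 0.0999). PDC1 rose by 2.80 ± 0.33 and 2.71 ± 0.35, and the auxin-induced AIR1 fell (-7.21 ± 0.76 and -6.64 ± 0.93). No list passed. The genes changed numbered 9743 and 5681, the latter 1590 without T530 SiBs replicate 1 and 839 with only the compared libraries fitted.

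Mock roots of the genotypes already differed. T530 stood above T510 at day 3 in iron signal peptide genes, IMA1 by 4.67 ± 0.66 (at 0.0513 and 1.31 CPM) and IMA2 by 3.19 ± 0.51, in the nitrate transporter NRT2.1 (2.97 ± 0.64) and in VSP2 (4.95 ± 0.64), a jasmonate-responsive gene (n = 3 per group). The sucrose synthase gene SUS4 was lower (-1.52 ± 0.15 at day 3 and -1.47 ± 0.15 at day 6), the reference gene UBQ10 (-0.73 ± 0.12 and -0.61 ± 0.12), and PAI1 higher by 2.17 ± 0.14 and 2.17 ± 0.14. The immune receptor gene DAR4 was at least 4396-fold lower in T530 at day 3 and 4551-fold at day 6. All genotypes were counted on TAIR10, so sequence that differs in a line can lower its counts without lower expression. This limit holds for all differences between Mock groups of the genotypes given here. Phosphate starvation genes were lower in T530 at day 6 in 9 of 16 (10 adjusted over the list alone) (adjusted p = 0.528), such as PS2 (-2.08 ± 0.34). Genes differing numbered 4875 at day 3 (7955 with only the compared libraries fitted, 3246 thinned) and 6059 at day 6. Against Col-0 they numbered 7664 for T510 and 6457 for T530. All 11 photosynthesis genes were lower in T510 than in Col-0 (median -4.51, adjusted p = 0.986), as were 12 of 16 detoxification genes (0.986), UGT74E2 (-2.38 ± 0.34). UGT74E2 was lower in T530 too (-2.85 ± 0.35), and IRT1 higher by 2.97 ± 0.54. T530 stood above T510 at day 3 in 6 of 11 (10 adjusted over the list alone) photosynthesis genes, markers of shoot tissue (median 2.11, adjusted p = 0.979 with an estimated correlation), with sums of 148, 444 and 402 CPM against 32.3, 36.4 and 86.2. The same held for 5 of 9 (6 adjusted over the list alone) photorespiration and leaf markers, a list chosen after the data were examined (median 1.46, adjusted p = 0.69 with an estimated correlation), so a different amount of shoot tissue could give part of the Mock differences between the lines. Photosynthesis sums of Col-0 Mock ran from 439 to 1774 CPM, so the same limit holds for the genes counted against Col-0. ICS1, WRKY33 and FRK1 did not pass between Mock groups of day 3. No list passed.

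Whether the genotypes responded differently was tested as the difference between their changes. For Bs at day 3, aliphatic glucosinolate genes fell further in T530 than in T510, MAM1 (-3.86 ± 0.86) and CYP83A1 (-3.11 ± 0.47), and 11 of 14 (12 adjusted over the list alone) of the list differed this way (adjusted p = 0.134 with an estimated correlation; n = 3 per group). The flagellin receptor gene FLS2 changed by 3.20 ± 0.49 more in T530, and IMA1 by -7.40 ± 0.94. IMA1 has low counts, with 0.0101 to 0.104 CPM in T510 Mock and 1.09 to 1.57 in T530 Mock. With Bs it ran from 0.194 to 2.78 CPM in T510 and from 0.157 to 0.289 in T530. Part of its difference thus lies between the Mock groups. PAD3 (-0.96 ± 0.43), CYP71A12 (-0.50 ± 0.37) and ICS1 (0.42 ± 0.45) did not pass. In all, 4707 genes differed (1356 with a higher change in T530 and 3351 with a lower). This was 3126, 7312 and 2772 without T530 Bs replicates 1, 2 and 3, 1580 with only the compared libraries fitted, and 2898 thinned to the shallowest. With Bs the photorespiration and leaf markers, chosen after the data were examined, fell in 8 of 9 cases in T530. In T510 2 fell and 1 rose (adjusted p = 0.386 and 0.82 with an estimated correlation). A different amount of shoot tissue could therefore give part of the genes with a lower change in T530, which was not tested. For SiBs against Bs, 3040 genes differed, PBS3 by -2.48 ± 0.65 (1704, 5920 and 1532 without T530 Bs replicates 1, 2 and 3, and 1818 without T510 Bs replicate 3). This count was 57 with only the compared libraries fitted, and 1464 with all libraries thinned to the shallowest.

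For the endophyte at day 3 the genotypes differed in 79 genes, and the iron list passed, with 2 of 21 (3 adjusted over the list alone) lower in T530 (adjusted p = 0.045). IMA1 differed by -4.44 ± 0.83, from Mock levels that were already higher in T530. The count was 49 and 50 without T510 Mock replicates 1 and 2, 348 with only the compared libraries fitted, 172 with DESeq2 and 26 thinned. For SiBs at day 3, 415 genes differed, IMA1 by -5.54 ± 0.83. This was 194 without T530 SiBs replicate 3, 202, 214 and 275 without T510 Mock replicates 1, 2 and 3, and 202 and 221 without T530 Mock replicates 2 and 3. It was 262 with a replicate block, 858 with DESeq2 and 145 thinned. Camalexin genes did not differ as a list (0.993). Against Col-0, the SiBs response differed in 1091 genes in T510, with photosynthesis genes higher in 11 of 11 (0.139) and PER4 by 2.73 ± 0.47 (582 without Col-0 Mock replicate 1, 648 without T510 Mock replicate 2, 725 with a replicate block, 543 thinned). In T530 it differed in 258 genes (580 with only the compared libraries fitted, 533 with DESeq2, 103 thinned), with iron genes lower in 3 of 21 (7 adjusted over the list alone) (0.0225), IRT1 by -3.88 ± 0.75 and FRO2 by -2.92 ± 0.57. Photosynthesis sums ran from 439 to 1774 CPM in Col-0 Mock and from 138 to 298 in Col-0 SiBs. In T510 they ran from 32.3 to 86.2 and from 106 to 860.5. Unequal shoot tissue could therefore give part of the 1091 genes of T510 against Col-0, which was not tested. At day 6 the Si response differed in 2474 genes, SPX1 by 3.05 ± 0.41, from Mock levels of 57.4 CPM in T510 and 8.85 in T530, and UGT74E2 by -4.35 ± 0.47. This was 1630 without T510 Si replicate 2, 934 without the 4 libraries with 2 runs, 1590 thinned, and 1116 among genes whose Mock level did not differ between days in T510, a limit set because clock genes shifted more in T530. The SiBs response differed in 1258 genes, SPX1 by 3.73 ± 0.42 and IRT1 by -4.86 ± 0.84 (380 and 2145 without T530 SiBs replicates 1 and 2, 822 without T510 SiBs replicate 1). It was 628 without the 4 libraries with 2 runs, 691 thinned, 706 with the same limit and 1981 with DESeq2. Iron genes were lower there in 6 of 21 (11 adjusted over the list alone) (0.00174).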

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

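Tests chosen only after the results were seen are those of clock effects in one or both genotypes, of the ratio of light-harvesting to RBCS genes in T530, of depth by thinning, of scaling by the spread of fold changes, and the look at which libraries the splits exchange.

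Results in this part are differences between genotypes in the response to the same treatment, each found by a test of the difference. The Bs response at day 3 differed between T530 and T510 in 4707 genes (2772 to 7312 when single libraries are left out, the ends without T530 Bs replicates 3 and 2, with 3126 without replicate 1), and the Si response in 79 (49 and 50 without T510 Mock replicates 1 and 2). The SiBs response differed in 415 (194 without T530 SiBs replicate 3, 202, 214 and 275 without T510 Mock replicates 1, 2 and 3, and 202 and 221 without T530 Mock replicates 2 and 3), and SiBs against Bs in 3040 (1704, 5920 and 1532 without T530 Bs replicates 1, 2 and 3, and 1818 without T510 Bs replicate 3). At day 6 the Si response differed in 2474 (1630 without T510 Si replicate 2) and the SiBs response in 1258 (380 and 2145 without T530 SiBs replicates 1 and 2, and 822 without T510 SiBs replicate 1). Against Col-0, the SiBs response at day 3 differed in 1091 genes in T510 (582 without Col-0 Mock replicate 1 and 648 without T510 Mock replicate 2) and 258 in T530. The limits of unequal shoot tissue given above, for the Bs difference and for T510 against Col-0, hold here too. The iron deficiency list differed between T530 and T510 for Si at day 3 (adjusted p = 0.0450), for SiBs at day 6 (0.00174) and between T530 and Col-0 for SiBs at day 3 (0.0225).

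The differences between groups of 3 libraries, which leave out that of SiBs at day 6 (2 in T530), were compared with 100 splits of the libraries each uses, fitted alone. For Bs at day 3, 2 of the 100, the real one included, gave as many genes as the real 1580 (highest other 6615), and for SiBs 4 gave 367 or more (highest other 7153), so the share is under 0.05. For Si it was 5 (348 genes, highest other 11723), for SiBs against Bs 6 (57, highest other 5179) and for Si at day 6 5 (3520, highest other 13853). For SiBs it was 8 in T510 against Col-0 (911, highest other 8942) and 6 in T530 against Col-0 (580, highest other 9738). For these 5 the share is 0.05 or more, so it does not exclude chance, but it is no clean measure of chance either, because of a structure of the samples. All other splits with as many genes exchange unequal numbers of libraries in the 2 treatments, which adds part of the difference between genotypes to the response. In each case the 42 splits that exchange equal numbers gave at most 6 genes. These splits mix both genotypes in every group, which widens the spread, so low counts are built in and do not exclude chance.

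The comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. In each, no split other than the real one gave as many genes. For T510, real values were 14787 (Bs), 7145 (Si), 11571 (SiBs), 11098 (SiBs against Bs) and 4725 (SiBs against Si) at day 3 and 6033, 12268 and 9589 (Si, SiBs, SiBs against Si) at day 6. For T530 they were 16536, 4879, 12143, 13880 and 8644 in the same order at day 3, and 8409 (Si) at day 6. They were 13124 for SiBs in Col-0, and between Mock groups 7955 and 8532 (T530 and T510, days 3 and 6), 9913 (T510 and Col-0) and 9158 (T530 and Col-0). The highest other split gave 3 genes for SiBs against Si in T530 at day 3 and 0 in the rest.

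Clock genes differ between treated and Mock roots of T530 at day 6. Mean CCA1, a morning gene, was 30.3 CPM in Mock, 1.71 in Si and 3.06 in SiBs, and TOC1, an evening gene, 32.1, 176 and 186, while in T510 Si moved CCA1 from 38.8 to 15.0 and TOC1 from 23.8 to 29.4. The shift with Si was larger in T530 by a median of 1.89 log2 (10 of 10 clock genes past the threshold). This argues against a log2 change of the same size in both lines as the whole cause. It cannot decide on an equal shift in time, because Mock of day 6 differed between the lines. LHY was 46.8 to 54.0 CPM in T530 Mock and 111 to 129 in T510 Mock, PRR5 14.9 to 17.0 and 2.80 to 4.67. The following explanations cannot be told apart because labels give no harvest times. Treated roots may have been taken at another time of day than their Mock (correlation of the Si change with the Mock difference between days in T510, r = 0.269). Si may shift the clock by an equal time in both genotypes, or in both but more in T530. At day 3, when Mock was already evening-like, the median was -0.37. Si may also shift the clock in T530 alone. Against this, 6 of 10 clock genes passed the same way with Si in T510 (binomial p = 0.00346 with genes taken as independent). With SiBs 9 of 10 did (binomial p = 0.0103). The Si lists had adjusted p = 0.243 in T510, though, and another harvest time could also give both. Genes whose Mock level did not differ between days in T510 held 5036 of the 8954 day 6 Si calls in T530, 26.4% of these genes against 34.2% of all. For Si in T510 at day 6 the shares were 15.2% against 17.8%, and for Si in T530 at day 3 11.2% against 11.5%.

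Photosynthesis genes vary between libraries of one group, as in T510 SiBs of day 3 (860.5 CPM in replicate 2, against 106.0 in the lowest). Shoot tissue left on some roots is a candidate explanation: deviations within groups of the photosynthesis list and of other leaf genes, fixed after single photosynthesis genes had been seen, correlate (r = 0.820 over 47 libraries). In the Mock, Si and SiBs libraries of T530 at day 3 the ratio of light-harvesting to RBCS genes, 0.567 to 1.37, lies within 3 times of the 0.719 in Col-0 Mock replicate 1, the library with the highest markers, as shoot tissue would give. The Si and SiBs libraries of T510 at day 3, with 1.36 to 2.15, lie within it too, so the ratio alone does not single out shoot tissue. Shoot tissue stays open for the T530 Bs libraries, where the ratio reached 3.89 with RBCS sums of 17.2 CPM or less. It stays open for T530 at day 6 too, where 3 of the 4 libraries with RBCS sums over 100 CPM (132 to 213) lie over 3 times away, up to 4.55. That cannot decide, because the library compared with is of day 3, and all libraries of day 6 in both lines ran from 1.98 to 4.86. No biological explanation was tested.

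Most tested genes change between Bs and Mock at day 3, 17392 in T510 and 18746 in T530. Tables argue against 3 technical explanations of these counts as the whole cause: with all libraries thinned to the shallowest, 15378 and 16949 genes passed, and changes were almost unrelated to transcript length (rho = 0.00404 and -0.0256). Another scaling of the Bs libraries would add a constant to every log2 fold change, but the fold changes spread around their median by 5.74 and 6.81 standard errors, which no constant removes. The balance of risen and fallen genes does depend on the scaling, with 37.9% or 65.0% risen in T510 for constants of -0.25 or 0.25. A response to the pathogen may be the cause, as a hypothesis, and reads of the fungi in these libraries were not tested.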

How the results depend on the processing

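Tests chosen after the data were seen are thinning and the limit to genes whose Mock level did not differ between days in T510. Where a value moved, the cause was not tested unless stated.

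RLE factors, no filter and the strict filter kept the gene counts of all 29 comparisons within 1.5 times, with RLE between 0.941 and 1.04 times, and no median of all genes moved by over 0.1. TMM and RLE both centre the fold changes, so small shifts of these medians are built in and do not test the scaling. Of 2542 named gene results, 22 lost their call with RLE, 65 with no filter, 136 with a replicate block, 154 without the 4 libraries with 2 runs and 267 with thinning, as did 10 of 2499 with the strict filter, 15 of 2507 with DESeq2 and 252 of 2465 with only the libraries compared. None reversed.

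Fitting only the libraries compared gave 7145 and 4879 genes for Si in T510 and T530 at day 3, 4725 (T510, day 3) and 839 (T530, day 6) for SiBs against Si, and 7955 for the Mock groups of day 3. Differences between genotypes were then 1580 for Bs, 348 for Si, 57 for SiBs against Bs, and 580 for T530 against Col-0. These fits have fewer samples to estimate the spread, but counts moved both ways. The mean chi-square between 2 replicates, which grows with their spread and depth, also differed between groups of day 3. It was 47.3 to 165.9 in Bs and 17.5 to 26.8 in Si of T510, and 34.5 to 86.3 and 39.3 to 63.3 in T530. A spread per gene shared by all groups may count too many differences where replicates vary more and too few elsewhere, which was not tested.

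Without the 4 libraries with 2 runs, Si in T530 at day 6 gave 5558, and the differences at day 6 were 934 (Si) and 628 (SiBs), with fewer samples. DESeq2 gave differences of 172 (Si, day 3), 858 (SiBs, day 3), 1981 (SiBs, day 6) and 533 (T530 against Col-0). A replicate block gave 262 for SiBs at day 3 and 725 for T510 against Col-0.

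Depth limits the smaller counts. Thinned, the Mock groups of day 3 gave 3246, and the differences at day 3 were 2898 (Bs), 26 (Si), 145 (SiBs), 1464 (SiBs against Bs), 543 (T510 against Col-0) and 103 (T530 against Col-0), and 1590 (Si) and 691 (SiBs) at day 6. Limited to genes whose Mock level did not differ between days, T530 at day 6 gave 5036 (Si) and 8264 (SiBs), with differences of 1116 and 706. Fewer genes are not the whole reason, since the share fell too, from 34.2% to 26.4% and 47.8% to 43.3%. For the differences it fell from 9.46% to 5.84% and 4.81% to 3.70%. It also fell for Si in T510 at day 6, from 17.8% to 15.2%, and little for Si in T530 at day 3, from 11.5% to 11.2%. The limit keeps genes that a test did not call, which may be harder to detect in any comparison. The differences and Si in T510 also share T510 Mock libraries of day 6 with it. How much of the fall the limit itself brings cannot be told.

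List tests passed in 328 cases with the preset correlation and 384 with fry, with 58 among both, in 56 with a replicate block (54 shared) and in 60 with RLE (58 shared). With all called genes in place of 200, the medians in SiBs against Bs were -0.69 and 1.00 (raised and lowered by Bs in T510) and -0.62 and 0.63 (in T530), since smaller changes enter. Correlations of responses across genotypes over genes with a mean of at least 5 CPM were 0.924 (Bs), 0.875 (Si), 0.898 (SiBs), 0.879 (T510 and Col-0), 0.906 (T530 and Col-0), 0.905 (SiBs against Bs) and 0.728 (SiBs against Si) at day 3, and 0.738, 0.873 and 0.741 (Si, SiBs, SiBs against Si) at day 6. Over all tested genes they were 0.817, 0.751, 0.780, 0.726, 0.777, 0.758, 0.519, 0.631, 0.759 and 0.611.

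Leaving out single libraries gave ranges of 7919 to 11888 (SiBs, T530 day 6), 4244 to 8285 (SiBs against Si, T510 day 3) and 1590 to 5808 (SiBs against Si, T530 day 6). Differences between genotypes ranged from 2772 to 7312 (Bs), 49 to 65 (Si), 194 to 496 (SiBs), 1532 to 5920 (SiBs against Bs) and 582 to 1105 (T510 against Col-0) at day 3, and from 1630 to 2705 (Si) and 380 to 2145 (SiBs) at day 6. The ends at day 6 for T530 SiBs are without its replicates 1 and 2, where the lone sample is assumed to vary like the other groups. Of 17269 named gene values 1831 lost their call and 3 reversed. PDF1.2A in T510 at day 6 ran from -1.13 to 9.98 for SiBs against Mock and from -0.73 to 9.97 for SiBs against Si, the low ends without T510 SiBs replicate 1. AT2G34840, in the difference for Si at day 6, ran from -2.33 (without T530 Si replicate 2) to 6.94.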

Other observations

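The lists and genes in this part were chosen after their values were seen, and no explanation was tested.

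Some genes had at most 3 counts over all libraries of one genotype and a mean of at least 5 CPM in another. Between T510 and T530 there were 3 such genes lacking in T510 and 4 in T530, between T530 and Col-0 17 lacking in T530 and 6 in Col-0, and between T510 and Col-0 1 lacking in T510 and 8 in Col-0. AT3G61010 averaged 134 CPM in T530 Mock and 38.3 in Col-0 Mock of day 3, and was at 0 in T510 Mock of day 3, though AT3G61010 reached 1.42 CPM in one T510 SiBs library of day 6. DAR4 averaged 42.8 CPM in T510 Mock and 33.1 in Col-0 Mock of day 3, and was at 0 in T530 Mock, though DAR4 reached 0.144 CPM in one T530 Bs library. Both genes fall outside the counts above. All genotypes were counted on TAIR10, so low counts in a line can also come from reads that did not map. IMA1, named among the differences between genotypes, has low counts: 0.0513 CPM in T510 Mock and 1.31 in T530 Mock of day 3.

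In T530 at day 6, Si raised 6 of 6 evening clock genes (median 2.23, adjusted p = 8.3e-08 over the 6 lists) and lowered 4 of 4 morning clock genes (-2.87, 4.6e-05). SiBs gave 6 of 6 and 4 of 4 there (4.0e-05 and 0.0102). In T510 Si gave 3 of 6 (4 adjusted over the list alone) and 3 of 4 (0.243 and 0.243), and SiBs 6 of 6 and 3 of 4 (0.0435 and 0.44). The photorespiration and leaf markers differed in the SiBs response of T510 against Col-0, with 7 of 9 higher (0.0934). With Bs at day 3, dark-inducible genes rose in 8 of 8 in T510 and 8 of 8 in T530 (medians 4.74 and 5.99, adjusted p = 0.482 and 0.376), heat shock genes in 8 of 9 and 9 of 9 (5.89 and 4.98, 0.482 and 0.386) and autophagy genes in 6 of 9 and 8 of 9 (0.482 and 0.386). In SiBs against Mock at day 6, dark-inducible genes rose in 8 of 8 in T530 (0.043) and 8 of 8 in T510 (0.264). Si alone gave 6 of 8 up in T530 (0.276) and 1 up and 1 down in T510 (0.723), and this Si response was higher in T530 in 4 of 8 (6 adjusted over the list alone), with adjusted p = 0.0502. Summed levels in T530 Mock were 640 to 936 CPM at day 3, when clock genes were evening-like, and 174 to 337 at day 6. With Si at day 6 they were 1188 to 1430. Another harvest time, raised above for the clock genes, could therefore give part of this rise, which was not tested. In SiBs against Si of T510 at day 6, dark-inducible genes rose in 8 of 8 (0.0603), heat shock genes in 5 of 9 (6 adjusted over the list alone) (0.626) and autophagy genes in 5 of 9 (8 adjusted over the list alone) (0.301). In T530 at day 6 dark-inducible sums were higher too, 3011 and 5736 CPM in SiBs and 1188 to 1430 in Si. At day 3 these sums were lower in SiBs than in Bs, 527 to 672 against 4141 to 8169 CPM in T510. In T530 they were 1004 to 1654 against 5883 to 14573.

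PDF1.2A at day 6 rested on single libraries, from 0.0998 to 49.6 CPM in T530 SiBs and from 0.0114 to 4.61 in T510 SiBs.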
